A study of Mus musculus with 20 samples.

How the data were processed

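Gene expression was measured on 20 Affymetrix mouse gene arrays of endothelial cells (CD31+CD45-Ter119-) sorted from collagenase-digested ears. Per the labels, mice received 5 tamoxifen injections, were sensitised with DNFB, were challenged on the ear on day 5, and ears were taken 24 hours later. Per the labels, 1 ng of total RNA was amplified with the WT Pico kit. Groups were taken from the sample titles: control vehicle 6, control DNFB 6, NICD vehicle 4 and NICD DNFB 4 arrays. NICD vehicle replicate 4 is vehicle by its title and DNFB by its description; it was kept as vehicle, and its values lay with the vehicle arrays on the first principal component. The genotype label names a Pdgfb-driven Cre and the growth protocol a Cdh5-driven Cre, and this was left open.

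The deposited values are log2 robust multi-array average (RMA) values per probe set, made by the authors in Affymetrix Expression Console per the labels; versions, options and annotation are not stated. The lowest value per array was 0.412 to 0.590 in control arrays and 1.18 to 1.30 in NICD arrays, a difference that a single normalization of all 20 arrays would not be expected to leave. No raw intensities were used. Precision between replicates of a group was a median absolute log2 difference of 0.249 to 0.348 between arrays.

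The table held 41345 probe sets: 23521 with 1 gene symbol, 1814 with several and 16010 with none. Kept were probe sets with 1 symbol whose value exceeded the array's median on at least 4 arrays, which left 14886 probe sets of 14178 genes. A model with 1 mean per group was fitted to all 20 arrays with limma 3.58.1 in R 4.3.3, with moderated tests, Benjamini-Hochberg adjustment over the probe sets kept and a threshold of adjusted p 0.05. The comparisons were DNFB against vehicle in each genotype, NICD against control in DNFB and in vehicle ears, and the difference of the DNFB effects. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

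Before the data were examined, 33 lists of genes and cell type markers were written, with 503 symbols, of which 435 were measured above the filter. Each list was tested in each comparison (165 tests) with camera at a preset correlation between genes of 0.01, Benjamini-Hochberg adjusted over all tests. Camera with an estimated correlation and the rotation test fry were run beside it. Camera compares a list with all other genes, whereas fry tests its members against 0. Members were counted past the threshold adjusted over all probe sets and over the list alone, with the probe set of highest mean standing for a gene. Of 58 list results that passed with the preset correlation, 2 also passed with an estimated one.

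Named genes follow a rule also written beforehand: Notch1; in each comparison the 8 largest rises and 8 largest falls past the threshold; up to 4 members past it from each list; and any measured Notch, adhesion, chemokine or cytokine gene. Predicted and small RNA genes and sex genes were excluded. Xist, Eif2s3y and Cdh5 fall outside the rule and were named after their values were seen, to describe sex and the pan-endothelial list. Krt14, Krt10, Dsp, Lor and Mmp9 were also named after their values were seen, to describe keratinocyte and neutrophil markers.

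The procedure was tested on simulated data with 200 changed genes. Differences of 1 log2 unit were recovered in 85.1% of cases for DNFB in control mice, 85.1% and 76.1% for NICD against control in DNFB and vehicle ears, 76.1% for DNFB in NICD mice and 55.2% for the difference of effects. Differences of 0.5 were recovered in 31.3%, 32.8%, 23.9%, 14.9% and 2.99%. Unchanged genes made up 2.70% to 8.85% of those past the threshold. Of 100 random lists of 20 genes, 3 gave a camera p under 0.05. The simulated genes were drawn independently of each other. In the measured data the estimated correlation was 0.0312 for Notch genes, 0.128 for chemokines, 0.412 for pan-endothelial markers and 0.702 for antigen presentation genes. The simulation therefore does not test camera on correlated lists.

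Alternatives were no filter and a stricter one at the 60th percentile, all probe sets with or without a symbol, quantile normalization, median centring or cyclic loess of all arrays, trended and robust variances, array weights, only the groups compared, replicate number as a fixed or random block, each array left out, and an added 2-fold limit. After the data were seen, 1 alternative was added: control replicates 1, 2, 3 and 5 left out for the H2 genes. Sex as a covariate was planned and could not be fitted, because each genotype held 1 sex. Correlations across probe sets carry no p, since probe sets are not independent. Probe sets with several symbols or none were left out of the gene results.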

Results

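Ear endothelial cells sorted as CD31+CD45-Ter119- were profiled 24 hours after a hapten challenge (DNFB) or vehicle, in control mice and in mice with inducible endothelial overexpression of the Notch1 intracellular domain (NICD mice). The groups held 6 control vehicle, 6 control DNFB, 4 NICD vehicle and 4 NICD DNFB arrays. All differences are on the log2 scale, given with ± 1 SE, and p-values are limma p-values adjusted over 14886 probe sets of 14178 genes. The first component of the data, 43.8% of the variance, followed DNFB, and the second, 21.6%, followed genotype. Between replicates of a group the array correlation ran from 0.944 to 0.981.

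**Figure D1:**
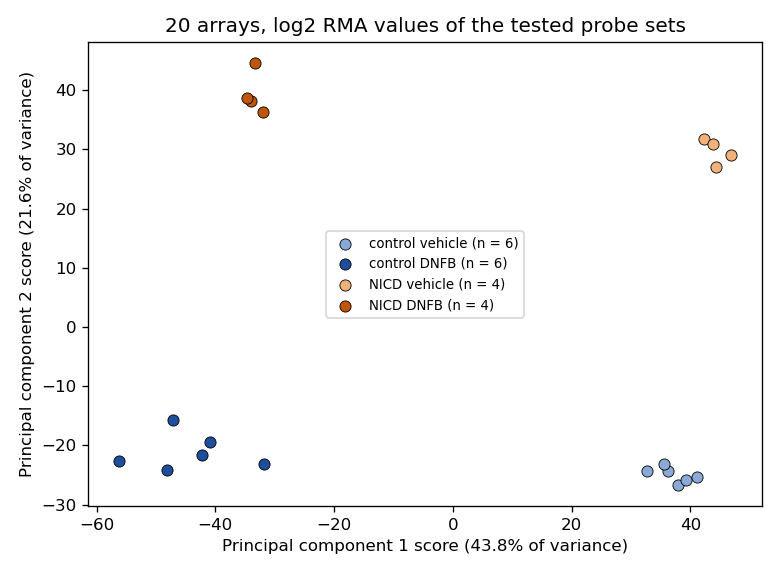
First and second principal components of the 20 arrays over the probe sets kept. Colour gives the group.

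Genotype was not separable from sex or from the array set. Xist ran from 2.27 to 3.16 in the control arrays and from 8.47 to 9.07 in the NICD arrays, and Eif2s3y averaged 6.75 and 6.79 (vehicle, DNFB) against 2.39 and 2.44, so that the control arrays read as male and the NICD arrays as female. The array medians were 3.87 to 3.98 in control arrays and 3.52 to 3.62 in NICD arrays. Comparisons of DNFB with vehicle within a genotype lie inside a set. The difference between those effects sets one array set and sex against the other, so a different response by sex or a different scale of the sets would enter it. Comparisons of NICD with control also cross the sets. Their gene differences in the main fit, where a size is given, stand beside the value after centring the arrays on their medians. Some genes are named as higher or lower without a size, and no centred value stands beside them. Fits against only some of the control arrays used uncentred values.

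Notch1 itself (probe set 17383052) did not pass the threshold between the genotypes. Its mean ± SD was 9.82 ± 0.12 in control vehicle, 9.76 ± 0.14 in control DNFB, 9.71 ± 0.16 in NICD vehicle and 9.76 ± 0.10 in NICD DNFB arrays. Relative to the median, Notch1 was 0.30 higher in NICD than in control DNFB ears (adjusted p 0.0543) and 0.20 higher in vehicle ears (adjusted p 0.22). The part of the transcript that its probes cover is not given, and the sign of the genotype difference turned between scalings, so this value does not check the transgene.

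In control mice, DNFB raised inflammatory chemokines and lowered genes of the resting capillary bed. The neutrophil chemokine Cxcl3 (probe set 17438975) rose by 6.99 ± 0.27 (adjusted p 4.67e-13), from a mean of 2.19 to 9.18. It started at background (receptor genes not known in skin had a median of 2.31 in control vehicle ears, most of them under 3.44), so its size is a lower bound and its rank is not read, as for Slc7a11 (from 2.60), Csta3 (from 2.95), Krt16 (from 2.34), S100a8 (from 3.20), Cxcr2 (from 3.38), Itgam (from 3.22) and Ptgs2 (from 3.13). The cystine transporter Slc7a11 rose by 6.03 ± 0.25 (adjusted p 1.13e-12), the matrix gene Tnc by 5.32 ± 0.20 (adjusted p 4.67e-13) and the cystatin Csta3 by 6.10 ± 0.31 (adjusted p 1.99e-11). The neuropeptide receptor Npy1r fell by 3.11 ± 0.13 (adjusted p 2.26e-12), Sult1a1 fell by 3.09 ± 0.24 (adjusted p 3.13e-09) and the natriuretic peptide receptor Npr3 fell by 2.89 ± 0.16 (adjusted p 3.85e-11). In all, 7033 probe sets passed, 3525 higher and 3508 lower, of which 829 and 864 changed at least 2-fold.

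Of 27 chemokines and cytokines in control mice, 21 rose, 2 fell and 4 did not pass (22 and 2 adjusted over the list alone; camera adjusted p 5.71e-07). With an estimated correlation between genes the adjusted p was 0.127. Cxcl5 rose by 4.67 ± 0.23, Il1b by 3.49 ± 0.43, Il11 by 3.48 ± 0.19 and Cxcl9 by 3.66 ± 0.44, while Cxcl12 fell by 1.54 ± 0.11 and Il15 fell by 0.94 ± 0.17. Neutrophil markers moved with them: 7 of 7 rose (S100a8 by at least 4.99 ± 0.30, Cxcr2 by at least 2.48 ± 0.28, camera adjusted p 9.88e-05, 0.127 with an estimated correlation). Only 7 of the 12 listed neutrophil markers passed the filter. In control vehicle ears S100a8, Cxcr2, Csf3r, Mmp9, Retnlg and Mmp8 averaged 2.73 to 3.77, under the control array medians of 3.87 to 3.98. They were thus kept mostly through brighter DNFB arrays, which favours a count of rises. Of 12 macrophage markers 8 rose (Itgam by 2.25 ± 0.21; adjusted p 0.00447, 0.349 estimated), and 5 of 5 platelet markers rose (Ppbp by 3.28 ± 0.43; adjusted p 0.00917, 0.343 estimated). Ptprc, which encodes the CD45 the sort excludes, rose by 1.21 ± 0.26 to a mean of 5.00.

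Capillary genes of control mice fell together. Of 16, 14 fell, 1 rose and 1 did not pass (14 and 1 adjusted over the list alone; camera adjusted p 4.42e-07, 0.0131 with an estimated correlation). Timp4 fell by 3.06 ± 0.17, the glycerol channel Aqp7 fell by 2.97 ± 0.20, Cd300lg fell by 2.68 ± 0.16 and the fatty acid transporter Cd36 fell by 2.23 ± 0.15. The carbonic anhydrase Car4 rose by 2.35 ± 0.20. Of 15 pan-endothelial markers 13 fell and none rose (Tek fell by 1.97 ± 0.16, Fli1 fell by 1.62 ± 0.12, Pecam1 fell by 0.21 ± 0.07; adjusted p 4.47e-05, 0.343 estimated). Of 11 pericyte markers 10 fell (Higd1b fell by 2.89 ± 0.18; adjusted p 0.000365, 0.344 estimated).

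Notch genes of control mice fell with DNFB: of 22, 16 fell, 2 rose and 4 did not pass (16 and 2 over the list alone; camera adjusted p 0.00019, 0.096 with an estimated correlation). Jag2 fell by 1.69 ± 0.15, Heyl fell by 1.65 ± 0.23, Sox17 fell by 1.45 ± 0.15 and Hey1 fell by 0.93 ± 0.10, and Il33 rose by 1.40 ± 0.22 and Dll1 by 0.79 ± 0.14. Arterial genes, 7 of which are also in the Notch list, fell in 16 and rose in 2 of 25 (17 and 2 over the list alone; adjusted p 0.000218, 0.219 estimated), with Bmx decreased by 1.85 ± 0.19. Venous genes fell in 9 and rose in 1 of 14 (9 and 2 over the list alone; adjusted p 0.0264, 0.147 estimated), with Aplnr decreased by 1.86 ± 0.23. Junction genes fell in 12 and rose in 2 of 19 (adjusted p 0.00768, 0.339 estimated).

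Adhesion molecules of control mice were split: of 22, 3 rose, 13 fell and 6 did not pass, and the list as a whole did not pass (camera adjusted p 0.0693). E-selectin (Sele) fell by 1.65 ± 0.15, Jam2 fell by 2.00 ± 0.14, Icam1 fell by 0.58 ± 0.14 and Selp fell by 0.46 ± 0.10. Cd44 rose by 3.05 ± 0.20 and Alcam by 1.26 ± 0.22. Vcam1 was 0.69 ± 0.29 higher and did not pass (adjusted p 0.0557).

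Coagulation, cell cycle and glycolysis lists of control mice passed upward with DNFB relative to all genes, none of them with an estimated correlation. Of 17 coagulation and vessel tone genes 9 rose and 5 fell (adjusted p 0.0445, 0.316 estimated), with Ptgs2 up by at least 4.44 ± 0.24, tissue factor F3 by 3.00 ± 0.21 and Procr by 2.23 ± 0.12 among the rises. That list did not pass without control vehicle replicate 1 or control DNFB replicate 3 (highest adjusted p 0.0723). Of 38 cell cycle genes 18 rose, none fell and 20 did not pass (Hells by 1.18 ± 0.16; adjusted p 0.0128, 0.523 estimated), and of 14 glycolysis genes 9 rose and 2 fell (Pgk1 by 1.77 ± 0.12; adjusted p 0.0264, 0.413 estimated, and 0.0502 without control DNFB replicate 2). Genes of the immediate early and dissociation list fell in 15 and rose in 2 of 22 (Fosb fell by 1.18 ± 0.12; adjusted p 0.00148, 0.451 estimated). Whether tissue digestion contributed to this fall was not tested.

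Keratinocyte markers of control mice did not pass as a list (3 rose and 2 fell of 11; camera adjusted p 0.556), though Krt16 rose by at least 5.93 ± 0.42, Krt6a by 4.82 ± 0.48 and Krt17 by 3.61 ± 0.54, and Krt15 fell by 2.03 ± 0.26. Lists not passing in control mice were tip cell (10 rose and 6 fell of 23; adjusted p 0.469), interferon response (6 and 3 of 31; 0.558), antigen presentation (1 and 0 of 18; 0.803), NF-kB (10 and 4 of 17; 0.0681), basement membrane (6 and 7 of 19; 0.388), mesenchymal transition (3 and 7 of 16; 0.188) and unfolded protein response (11 and 1 of 17; 0.0501). Nor did the markers of lymphatic endothelium (adjusted p 0.186), fibroblasts (0.186), T and NK cells (0.559), mast cells (0.831), erythroid cells (0.873), melanocytes and Schwann cells (0.803), skeletal muscle (0.86), chondrocytes (0.86) or adipocytes (0.719).

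**Figure D2:**
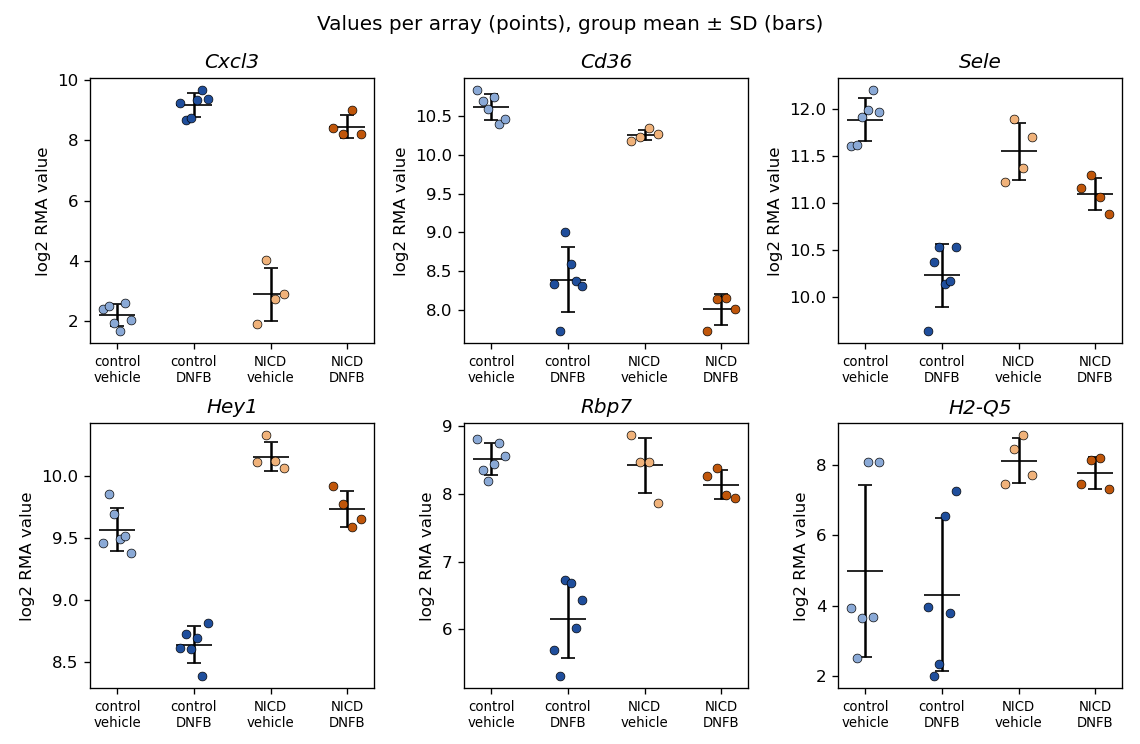
Log2 values of Cxcl3, Cd36, Sele, Hey1, Rbp7 and H2-Q5 on every array, by group. Genotype is inseparable from sex and array set.

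In NICD mice, DNFB moved largely the same genes. Cxcl3 rose by 5.58 ± 0.33 (adjusted p 6.23e-10), Krt16 by 5.10 ± 0.52, Krt6a by 4.82 ± 0.59, Slc7a11 by 4.64 ± 0.31, Tnc by 4.62 ± 0.25 and Il1b by 4.51 ± 0.52. Of these, Cxcl3 (from 2.88), Krt16 (from 2.97) and Slc7a11 (from 2.64) started at background (receptor median 2.49 in NICD vehicle ears, most under 3.18), and their rises are lower bounds. Fmo2 fell by 3.99 ± 0.29 (adjusted p 4.24e-09), C1qtnf9 fell by 3.31 ± 0.17, Npy1r fell by 2.99 ± 0.16 and Timp4 fell by 2.98 ± 0.21. In all, 5665 probe sets passed, 2974 higher and 2691 lower, of which 828 and 791 changed at least 2-fold. Higher in both genotypes were 2428 probe sets (704 if the genotypes were independent), lower in both 2239 (634), and 16 passed in opposite directions.

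Of 27 chemokines and cytokines in NICD mice, 18 rose and 2 fell (21 and 2 over the list alone; camera adjusted p 7.02e-08, 0.122 with an estimated correlation), among them Cxcl9 by 4.47 ± 0.54, Cxcl10 by 3.77 ± 0.26 and Ccl2 by 3.57 ± 0.27. Neutrophil markers rose in 6 of 7 (S100a8 by 4.37 ± 0.37; adjusted p 0.000242, 0.147 estimated) and macrophage markers in 7 of 12 (adjusted p 0.00276, 0.344 estimated). Capillary genes fell in 13 and rose in 1 of 16 (Cd300lg fell by 2.57 ± 0.19, Cd36 fell by 2.25 ± 0.18, Car4 rose by 2.23 ± 0.24; adjusted p 3.01e-06, 0.0144 estimated). Pericyte markers fell in 8 of 11 (adjusted p 0.000183, 0.339 estimated).

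Of the 22 Notch genes in NICD mice 11 fell, 2 rose and 9 did not pass (11 and 3 over the list alone; camera adjusted p 0.012, 0.181 with an estimated correlation): Hey2 fell by 1.25 ± 0.20, Lfng fell by 1.18 ± 0.12, Jag2 fell by 0.84 ± 0.18 and Hey1 fell by 0.42 ± 0.12. Junction genes fell in 10 and rose in 2 of 19 (adjusted p 0.0357, 0.413 estimated, and 0.0532 without NICD DNFB replicate 4). Pan-endothelial markers fell in 9 and rose in 1 of 15 (Tek fell by 1.45 ± 0.19; adjusted p 0.0114, 0.561 estimated). Sele (-0.45 ± 0.19, adjusted p 0.0638) and Heyl (-0.51 ± 0.28, adjusted p 0.175) did not pass, and Vcam1 rose by 2.12 ± 0.35 (adjusted p 6.87e-05).

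Other lists rose with DNFB in NICD mice. Unfolded protein response genes rose in 10 and fell in 1 of 17 (Sdf2l1 by 2.40 ± 0.29; adjusted p 0.00236, 0.152 estimated), interferon response genes in 13 and 2 of 31 (Isg15 by 0.88 ± 0.26; adjusted p 0.0169, 0.777 estimated) and NF-kB genes in 9 and 0 of 17 (adjusted p 0.0153, 0.344 estimated). The interferon list did not pass without NICD vehicle replicate 1 or NICD vehicle replicate 4 (highest adjusted p 0.0619). Cell cycle genes rose in 13 of 38 (adjusted p 0.00196, 0.413 estimated), glycolysis genes in 8 of 14 with 1 lower (0.0102, 0.349 estimated) and coagulation genes in 9 of 17 with 3 lower (Ptgs2 by at least 3.44 ± 0.30, from 3.11; 0.00768, 0.152 estimated). Immediate early and dissociation genes fell in 16 and rose in 2 of 22 (adjusted p 0.000157, 0.349 estimated).

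**Figure D3:**
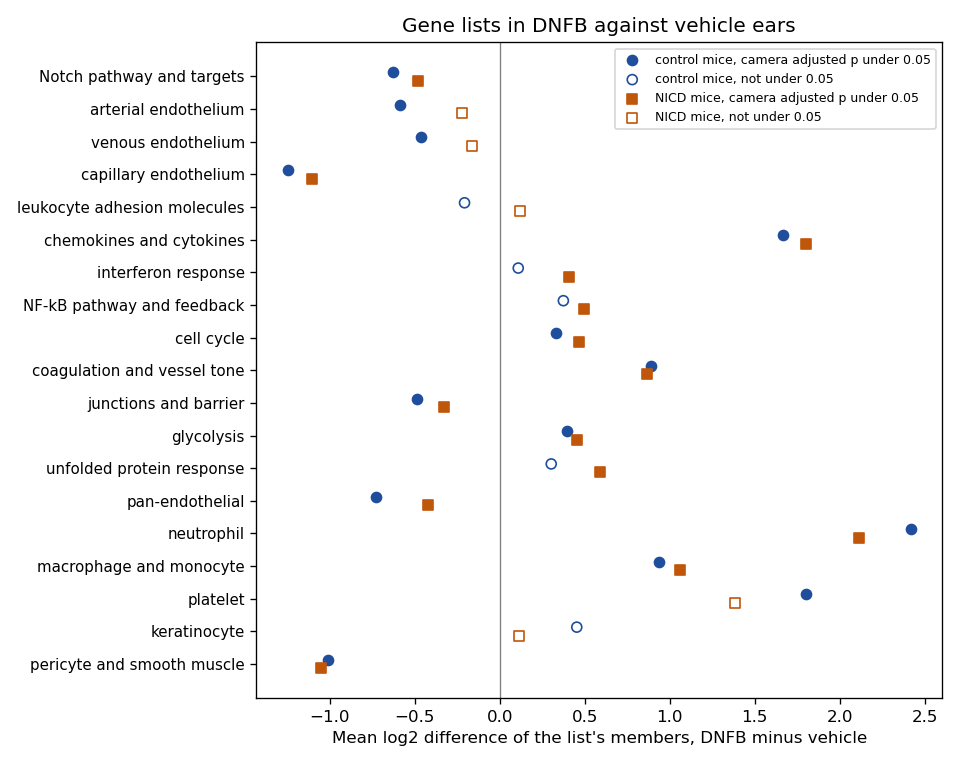
Mean log2 difference between DNFB and vehicle ears of the members of selected gene and marker lists, in control mice (circles) and NICD mice (squares). Filled symbols passed with camera at the preset correlation.

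The difference of the DNFB effects between the genotypes, tested directly, passed for 2 genes with limma. Rbp7 (probe set 17433145) fell by 2.37 ± 0.22 in control mice and did not pass in NICD mice (-0.28 ± 0.26), a difference of 2.09 ± 0.34 (adjusted p 0.0423). Mpp7 (probe set 17352549) rose by 0.82 ± 0.14 in control and fell by 0.66 ± 0.17 in NICD mice, a difference of -1.48 ± 0.22 (adjusted p 0.0274). After centring, Rbp7 differed by 2.08 ± 0.35 (adjusted p 0.0521) and Mpp7 by -1.49 ± 0.23 (adjusted p 0.0502), so that neither passed while the sizes hardly moved. Leaving out 1 array, Rbp7 ran from 1.91 to 2.24 and Mpp7 from -1.58 to -1.35, and they did not pass in 15 and 9 of 20 fits. At an unadjusted p under 0.05 there were 1580 probe sets, where 744 are expected by chance. Sele differed by 1.20 ± 0.24 (adjusted p 0.0839), Il15 by 1.35 ± 0.26 (adjusted p 0.0839), Kdr by 0.74 ± 0.16 (adjusted p 0.0899), Vcam1 by 1.43 ± 0.46 (adjusted p 0.273) and Jag2 by 0.85 ± 0.24 (adjusted p 0.181), without passing in this fit. Sele, Il15 and Kdr passed with trended and robust variances (adjusted p 0.0328, 0.0292 and 0.0212). With replicate number as a random block 20 genes passed, with Rbp7, Mpp7, Sele, Il15 and Kdr among them. As a fixed block it kept Mpp7 (adjusted p 0.0275) but not Rbp7.

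Arterial, adhesion, pan-endothelial and venous lists had a more positive DNFB effect in NICD than in control mice, none of them with an estimated correlation. Arterial genes differed by 0.36 relative to all genes (camera adjusted p 4.87e-06, 0.131 with an estimated correlation), adhesion molecules by 0.32 (from -0.21 in control to 0.11 in NICD mice, where they did not pass; adjusted p 5.16e-05, 0.152 estimated) and pan-endothelial markers by 0.29 (adjusted p 6.35e-05, 0.344 estimated). Adjusted over the list alone, 9 arterial genes passed with a positive difference and 0 with a negative one (Gja4 0.82 ± 0.19, Vegfc 1.04 ± 0.27), 8 and 1 adhesion molecules, and 5 and 0 pan-endothelial markers. None passed over all genes in the main fit, though Sele, Kdr and Gja4 were among those that did with trended and robust variances. Venous genes differed by 0.29 (0.0136, 0.127 estimated, 4 and 1 over the list alone), while capillary genes (0.14, adjusted p 0.173, 0.412 estimated, 1 and 0) and junction genes (0.15, adjusted p 0.0898) did not pass. Interferon response genes differed by 0.29 (0.000889, 0.658 estimated, 0 and 0), unfolded protein response genes by 0.28 (0.00204, 0.152 estimated, 3 and 0) and basement membrane genes by 0.21 (0.00325, 0.28 estimated, 2 and 0). Notch genes differed by 0.14 (0.0409, 0.316 estimated, 8 and 1), tip cell genes by 0.038 (0.0445, 0.572 estimated, 4 and 1) and lymphatic markers by -0.33 (0.0359, 0.642 estimated, 0 and 0), and these 3 lists did not pass in 8, 9 and 8 of 20 fits leaving out an array (highest adjusted p 0.124, 0.159 and 0.343).

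Across probe sets the DNFB effects of the genotypes, which share no array, correlated with r 0.876 (jackknife SE 0.0237) and rho 0.821. The slope was 0.878 (jackknife SE 0.0372) over only the probe sets that passed for DNFB in control mice. That choice by itself can pull the slope down. With the choice and the control effect taken from separate control arrays, the slope was 0.884 and 0.899. The NICD difference in DNFB ears and the DNFB effect in control mice correlated with r -0.208 and covariance -0.0635. They share the control DNFB arrays, and simulated unchanged groups that share them too gave a mean r of -0.444 and covariance of -0.0154. That simulation held no DNFB effect, so its r cannot be set against the observed r. On split control arrays r was -0.210 and -0.0669 for the 2 splits (mean -0.139) and the covariance -0.0667 and -0.0237 (mean -0.0452). The split differences share no array, so the simulated values are no reference for them, and unchanged groups would give no correlation there on average.

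In DNFB ears, NICD and control arrays differed in many genes, in arrays that also differ in sex and set. The natriuretic peptide receptor Npr3 was higher by 2.40 ± 0.18 (centred 2.70; adjusted p 2.52e-08) and Dad1 by 1.93 ± 0.12 (centred 2.23; adjusted p 2.82e-09). Stmn2 was higher by 1.85 ± 0.25 (centred 2.15), Sema3g by 1.73 ± 0.22 (centred 2.03), Vegfc by 1.38 ± 0.19 (centred 1.67) and Efnb2 by 0.86 ± 0.11 (centred 1.16). The Notch target Hey1 was 2.14-fold higher (log2 centred 1.39; adjusted p 1.64e-06). Lower were Arap2 (-2.21 ± 0.14, centred -1.91), Trp53i11 (-2.03 ± 0.27, centred -1.73), Cd226 (-1.88 ± 0.27, centred -1.58) and the Notch target Hes1 (-0.85 ± 0.14, centred -0.55). Of 14886 probe sets 6036 passed, 811 higher and 5225 lower, around a median shift of -0.27, and after centring 4060 passed, 2455 higher and 1605 lower. After quantile normalization 1778 were higher and 1775 lower, so the prevailing direction depended on the scaling.

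Relative to all genes in DNFB ears, arterial genes were higher in NICD arrays (10 higher and 1 lower of 25, centred 15 and 0, camera adjusted p 6.79e-09, 0.096 with an estimated correlation). The shift that varied with intensity may enter this and the other list results between genotypes. Notch genes passed as higher with 6 higher and 4 lower of 22, centred 11 and 3 (Hey1, Unc5b and Gja4 higher, Hes1 and Dll1 lower; adjusted p 0.000442, 0.118 estimated), tip cell genes with 9 and 2 of 23 (centred 12 and 1, adjusted p 4.87e-06, 0.181 estimated) and venous genes with 6 and 3 of 14 (centred 8 and 1, adjusted p 0.00938, 0.122 estimated). Adhesion molecules had 6 higher and 4 lower of 22 (centred 14 and 1, adjusted p 0.000565, 0.273 estimated): Jam2 was higher by 1.07 ± 0.16 (centred 1.36) and Sele by 0.87 ± 0.17 (centred 1.16), and Cd44 was lower (-0.85 ± 0.22, and -0.55 after centring, where it did not pass). Basement membrane genes had 7 higher and 2 lower of 19 (centred 10 and 0, Col18a1 1.44 ± 0.18, centred 1.74; 0.00019, 0.15 estimated), pan-endothelial markers 5 and 0 of 15 (centred 12 and 0, adjusted p 4.87e-06, 0.316 estimated) and lymphatic markers 5 and 0 of 10 (centred 7 and 0, Mmrn1 1.28 ± 0.32, centred 1.58, Lyve1 1.01 ± 0.24, centred 1.31; 1.01e-05, 0.316 estimated).

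Interferon response genes in DNFB ears had 10 higher and 2 lower of 31 (centred 15 and 0, Isg15 1.27 ± 0.24, centred 1.57; adjusted p 1.02e-07, 0.418 with an estimated correlation), and antigen presentation genes 8 higher and 0 lower of 18 (centred 11 and 0, adjusted p 5.71e-07, 0.392 estimated). H2-T23 was higher by 2.38 ± 0.63 (centred 2.67) and H2-Q5 (probe set 17337110) by 3.47 ± 1.08 (centred 3.76; adjusted p 0.0155), but in control DNFB arrays H2-Q5 averaged 6.91 in replicates 4 and 6 and 3.02 in the others, against 7.78 in NICD DNFB arrays. Against replicates 4 and 6 only, on uncentred values, neither H2-Q5 (adjusted p 0.114) nor H2-T23 (adjusted p 0.0744) passed. The antigen presentation list, which holds H2-T23 but not H2-Q5, was not retested against these replicates. Chemokines did not pass as a list (2 higher and 10 lower of 27, centred 4 and 8, adjusted p 0.86), with Il11 at -1.52 ± 0.21 (centred -1.22) and Cxcl5 at -1.49 ± 0.26 (centred -1.20). Capillary genes did not pass either (1 and 1 of 16, centred 3 and 1, adjusted p 0.0779).

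In vehicle ears, NICD against control differed in many of the same genes. Npr3 was higher by 2.18 ± 0.18 (centred 2.48; adjusted p 1.27e-07), Dad1 by 1.87 ± 0.12 (centred 2.17), Kcnn3 by 1.88 ± 0.25 (centred 2.19), Stmn2 by 1.42 ± 0.25 (centred 1.73), Unc5b by 0.90 ± 0.21 (centred 1.20) and Hey1 by 0.59 ± 0.11 (centred 0.90; adjusted p 0.000527). Lower were Cyp2d40 (-1.92 ± 0.23, centred -1.62), Csf3 (-1.87 ± 0.27, centred -1.56), Cxcl10 (-1.36 ± 0.23, centred -1.06) and Arap2 (-1.30 ± 0.14, centred -0.99). Hes1 was lower (-0.59 ± 0.14), and -0.28 after centring, where it did not pass (adjusted p 0.185). Of 14886 probe sets 5343 passed, 428 higher and 4915 lower, around a median shift of -0.28, and after centring 2778 passed, 1677 higher and 1101 lower. After quantile normalization 1020 were higher and 1392 lower, so here too the prevailing direction depended on the scaling. The genotype differences of DNFB and vehicle ears correlated with r 0.683, and after centring 1719 probe sets passed in both with the same direction and 8 with opposite directions.

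Lymphatic markers had the smallest p of the lists in NICD vehicle ears: 7 higher and 0 lower of 10, centred 8 and 0 (Reln 1.76 ± 0.27, centred 2.07, Mmrn1 1.72 ± 0.32, centred 2.02, Lyve1 1.35 ± 0.24, centred 1.66, Flt4 0.99 ± 0.23, centred 1.29; camera adjusted p 3.78e-11, 0.127 with an estimated correlation). Arterial, tip cell and Notch genes were higher relative to all genes. Arterial genes had 4 higher and 3 lower of 25 (centred 6 and 0, adjusted p 0.00303, 0.339 estimated), tip cell genes 6 and 4 of 23 (centred 9 and 1, Apln 1.16 ± 0.29, centred 1.46; 0.00475, 0.412 estimated) and Notch genes 4 and 7 of 22 (centred 6 and 0, mean 0.22 over all genes, adjusted p 0.0483, 0.33 estimated). The Notch list did not pass without control vehicle replicates 1, 4, 5 or 6, or NICD vehicle replicates 3 or 4, each alone (highest adjusted p 0.083). Also higher relative to all genes were antigen presentation genes, with 2 higher and 1 lower of 18 (centred 5 and 0, adjusted p 9.01e-05, 0.514 estimated), and interferon response genes, with 1 and 3 of 31 (centred 5 and 0, mean 0.29 over all genes, adjusted p 0.00236, 0.702 estimated, and 0.145 without control vehicle replicate 3). Against control replicates 4 and 6 only, on uncentred values, neither H2-Q5 (adjusted p 0.964) nor H2-T23 (adjusted p 0.769) passed in vehicle ears. The antigen presentation list, which holds H2-T23 but not H2-Q5, was not retested against these replicates. NF-kB genes were lower in 10 of 17 and higher in 0, and after centring in 4 and 0 (mean -0.19 against all genes; Tnfaip3 -0.86 ± 0.12, centred -0.56, Nfkbiz -0.86 ± 0.12, centred -0.55; 0.00986, 0.339 estimated). Keratinocyte markers had 1 higher and 1 lower of 11 (centred 1 and 0, adjusted p 0.0357, 0.642 estimated), and did not pass without control vehicle replicate 3 or 6, or NICD vehicle replicate 3 or 4 (highest adjusted p 0.14).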

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

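The values below were picked by rules fixed before the data were examined, and no test here was chosen after the result was seen. Of 128 combinations of group and value tested for an array standing apart, 15 did, where 6.4 are expected by chance.

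NICD vehicle replicate 1 was the highest of its group in arterial genes (7.90), coagulation and vessel tone genes (7.25) and basement membrane genes (9.18). NICD vehicle replicate 2 was the highest in adhesion molecules (8.12) and skeletal muscle markers (4.89) and the lowest in Notch1 (9.47). NICD vehicle replicate 3 was the lowest in T and NK cell markers (3.73). NICD DNFB replicate 4 was the lowest in adhesion molecules (8.06) and in melanocyte and Schwann cell markers (3.54), and NICD DNFB replicate 1 the highest in skeletal muscle markers (5.60).

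Among control arrays, vehicle replicate 3 was the highest in tip cell genes (8.92) and the lowest in fibroblast markers (6.04), vehicle replicate 2 the lowest in NF-kB genes (7.12) and vehicle replicate 4 the lowest in neutrophil markers (3.18). DNFB replicate 5 was the highest in macrophage markers (5.88). What set these arrays apart was not tested.

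The DNFB effect differed between the genotypes for Rbp7 (2.09) and Mpp7 (-1.48). Rbp7 no longer passed in 15 of 20 fits that left out an array, and Mpp7 in 9 of 20. Relative to all genes the effect differed for Notch genes (0.14), arterial (0.36), venous (0.29) and tip cell genes (0.038), adhesion molecules (0.32), interferon response (0.29), basement membrane (0.21) and unfolded protein response genes (0.28), pan-endothelial markers (0.29) and lymphatic markers (-0.33). With an estimated correlation between genes, none of these 10 lists passed.

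Of 8368 probe sets with no gene symbol above the filter, 1414 passed for DNFB in control mice, 697 higher and 717 lower, and were not analysed further. The flag covered that comparison only. For NICD against control 1998 passed in DNFB ears and 1511 in vehicle ears, and for DNFB in NICD mice 1212 passed.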

How the results depend on the processing

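The fit leaving out control replicates 1, 2, 3 and 5 was chosen after the result was seen; the others were planned. Sex could not be fitted as a covariate, since each genotype held 1 sex.

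NICD against control in DNFB ears passed for 6036 probe sets. After quantile normalization 3553 passed (1778 higher, 1775 lower), after cyclic loess 3597 (1769 higher, 1828 lower) and with a 2-fold limit 801. In vehicle ears the 5343 became 2412 after quantile normalization (1020 higher, 1392 lower) and 2778 after centring (1677 higher, 1101 lower). They became 2357 after cyclic loess (1235 higher, 1122 lower) and 503 with a 2-fold limit. With a 2-fold limit DNFB in control mice gave 1693 and in NICD mice 1619.

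The 2 genes whose DNFB effect differed became 1 without the filter, 0 with all probe sets, 1 after quantile normalization, 0 after centring, 1 after cyclic loess, 27 with trended and robust variances and 17 with array weights. Sele, Il15 and Kdr, which did not pass, passed with trended and robust variances (adjusted p 0.0328, 0.0292 and 0.0212) and with array weights (adjusted p 0.0447, 0.0323 and 0.0447). Leaving out an array gave 0 to 29: 29 without control DNFB replicate 6, 0 without control DNFB replicate 1, control vehicle replicates 4, 5 or 6, NICD vehicle replicates 1, 3 or 4, or NICD DNFB replicates 2 or 4, and 1 without control vehicle replicates 1 or 2, control DNFB replicate 5, NICD DNFB replicates 1 or 3, or NICD vehicle replicate 2.

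Leaving out an array gave 6674 to 7003 for DNFB in control mice, 4852 to 5970 and 4362 to 5213 for NICD against control in DNFB and vehicle ears, and 5054 to 5277 for DNFB against vehicle in NICD mice (5068 without NICD vehicle replicate 4, whose labels disagree). The correlation of the DNFB effects ran from 0.859 to 0.881 and was 0.837 without the filter and 0.780 with all probe sets; the slope ran from 0.856 to 0.890. The correlation of the NICD difference with the DNFB effect ran from -0.245 to -0.190, and was -0.139 on split control arrays (-0.210 and -0.0669 for the 2 splits).

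Against 0 instead of all genes (fry), list results for NICD against control in vehicle ears turned in direction: Notch genes had a mean of -0.065 and arterial (0.0025), tip cell (0.059) and interferon response genes (0.0064) a mean near 0, without passing. The median shift between the array sets lies in these means, and the cause was not tested.

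No named gene that passed turned in direction. Of the 390 gene values that passed, 54 no longer did after centring, 53 in at least 1 fit leaving out an array, 44 after cyclic loess, 41 after quantile normalization, 19 with a fixed block, 17 with all probe sets, 13 without the filter and 12 with only the groups compared. Of the 58 lists that passed, 56 no longer did with an estimated correlation, 10 in at least 1 fit leaving out an array, 10 with fry in the same direction, 10 after cyclic loess, 9 after quantile normalization and 6 without the filter. Receptor probe sets had a median level of 2.38, near background, so the rises of Cxcl3 from 2.19 and Krt16 from 2.34 are limited by the floor.

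Replicate number as a random block gave 20 genes with a different DNFB effect, Sele, Il15 and Kdr (adjusted p 0.0481, 0.0481 and just under the threshold) among them, and as a fixed block 3 (Mpp7, H2-T24 and Nat8l, not Rbp7). Arrays of equal number correlated with r 0.0418 to 0.269 (median 0.0969) after removal of group means, above 0 in 10 of 10 pairs and over 0.1 in 5. Not every array was closest to its own number, but 13 of 20 were, where 4 are expected by chance, which is a hint from the data, not the design, that some numbers mark a shared source. In control arrays of both treatments H2-Q5 was at least 6.56 in numbers 4 and 6 and at most 3.96 in the others. This pattern, picked after its values were seen, is a further hint for numbers 4 and 6. No label states a shared animal, so the numbers were not taken as pairs in the main fit. The count of genes with a different DNFB effect depended on this choice. The limit of 0.1 is no test of pairing, and a shared source stays open.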

Other observations

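Chosen after the result was seen were the tests on Xist, on Krt6a with Krt16, the fit against control replicates 4 and 6 only and, for the smaller fall of pan-endothelial markers, on a narrower scale, on a common shift and on markers of other cell types; the tests on receptor genes, keratinocyte markers and neutrophil markers and the regroupings were planned. The pattern of a smaller fall of pan-endothelial markers took the place of a planned one, a larger DNFB effect on interferon and antigen presentation genes in NICD mice, whose planned test for dim genes near the floor was not run.

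NICD arrays had shifted values against control arrays. After centring, 44.1% of olfactory and vomeronasal receptor probe sets, which skin endothelium is not known to express, passed between genotypes in vehicle ears (590 of 620 higher in NICD arrays), against 22.9% of all other probe sets with 1 symbol, 3.35% for DNFB in control mice and a bound of 10 set beforehand. A separate normalization or hybridisation of the array sets may therefore lie behind part of the genotype differences. The lowest Xist value of the NICD arrays exceeded the highest of the control arrays by 5.31, so sex and genotype cannot be told apart by design. The genotype comparisons of this series may hold effects of NICD, sex and array set together.

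Krt6a, Krt16 and Krt17 and neutrophil genes were higher in DNFB ears, though keratinocyte markers did not pass as a list. Keratinocyte genes were read in every group: in control vehicle and control DNFB ears Krt14 averaged 11.1 and 11.6 and Krt10 10.2 and 9.58. In NICD vehicle and NICD DNFB ears Krt14 averaged 11.1 and 11.3 and Krt10 10.2 and 9.55. Pecam1 averaged 11.7 in control vehicle ears, where Dsp (8.51) and Lor (5.26) were dimmer. Constitutive keratinocyte markers had a median difference of 0.31 (range -2.03 to 1.85) in control mice, between the bounds set beforehand. Whether DNFB raised the carry-over of keratinocytes was thus undecided. In NICD mice their median was -0.32 (range -1.79 to 1.32), while Krt6a and Krt16 rose by 4.82 and 5.10. In control mice Krt6a and Krt16 rose by 5.07 more than the control median, against an SD of 1.04 of the markers. Krt16 started at background, which makes this a lower bound, so more keratinocytes are unlikely to be the whole source of their rise. Which cells made these transcripts was not tested. Neutrophil markers other than S100a8 and S100a9 had a median difference of at least 1.71 in control mice, where Mmp9, at the median, started at background (3.32). These 5 markers averaged 2.73 to 3.77 in control vehicle ears, under the array medians. The filter kept them mostly through DNFB arrays, which favours a positive median. In NICD mice their median was 1.31. These rises were seen although the sort excludes CD45. More neutrophils or free neutrophil RNA among the sorted cells may be the source, and whether part of the chemokine rise has it too was not tested.

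Pan-endothelial markers as a list fell less with DNFB in NICD mice, by 0.29, but not with an estimated correlation (adjusted p 0.344). No marker passed over all genes in the main fit, though Kdr did with trended and robust variances (limma adjusted p 0.0212). Capillary genes did not pass (0.14, adjusted p 0.173) and lymphatic markers had the opposite sign (-0.33), which did not pass with an estimated correlation (adjusted p 0.642) or in 8 of 20 fits leaving out an array. A narrower scale of the NICD arrays (slopes on held-out control arrays 0.884 and 0.899) predicted less than was seen, by 0.22, which was only 2.06 SE and marginal. A common shift, which a higher share of endothelial cells might give, was not seen across the 15 pan-endothelial markers (heterogeneity p 0.000478 treating genes as independent, and 0.0273 without the bright Pecam1 and Cdh5). This argues against it as the whole cause only. As a part it stays open, since 10 lists of other cell types had a mean difference, weighted by precision, of -0.085 ± 0.089, with 5 of the 10 below 0. That SE treats the lists as independent, although all were measured on the same arrays, so it may be too small. Platelet (-0.43), keratinocyte (-0.35), fibroblast (-0.34) and neutrophil lists (-0.31) were among those below. Skeletal muscle (0.43), T and NK cell (0.13) and macrophage lists (0.12) were among those above, and none passed. Whether endothelial cells of NICD mice lost less of the pan-endothelial markers stays open, since the pattern was found and tested on the same arrays and is possibly tied to sex.

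H2-Q5 in control replicates 4 and 6 averaged 8.09 in vehicle and 6.91 in DNFB ears, against 3.44 and 3.02 in the other control arrays and a range of 7.32 to 8.84 in NICD arrays. Against control replicates 4 and 6 only, H2-Q5 differed between genotypes by 0.87 in DNFB ears (limma adjusted p 0.114) and 0.03 in vehicle ears (adjusted p 0.964). In DNFB ears H2-T23 (0.62, adjusted p 0.0744), H2-Ab1 (1.30 ± 0.61, adjusted p 0.141) and H2-Aa (1.32 ± 0.44, adjusted p 0.0515) did not pass either. With all control arrays H2-Q5 differed by 3.47, H2-Ab1 by 2.06 and H2-Aa by 1.83. H2-Ab1 and H2-Aa thus kept more of their size than H2-Q5, on fewer control arrays. These fits used uncentred values, and with all control arrays the median shift in DNFB ears was -0.27. That shift may enter the lost calls. What set these control arrays apart was not tested.

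Other splits of the arrays can exclude chance for the counts in 4 comparisons, fitted here with the compared groups alone. As many probe sets came from 1 of 100 splits for DNFB in control mice (real 6638, highest other 99), 1 of 100 for NICD against control in DNFB ears (5416, 154), 1 of 100 in vehicle ears (5249, 25) and 1 of 35 for DNFB in NICD mice (5697, 0). For the difference of the DNFB effects, 2 of 100 regroupings, the real one included, gave at least 2 genes, and the highest other gave 3, more than the real labels. The count was 0 after centring and in 9 of 20 fits leaving out an array, so nothing more is read from the count. The sizes hardly moved, at 2.08 for Rbp7 and -1.49 for Mpp7 after centring, and each adjusted p lay near the threshold. The splits of the genotype comparisons follow sex and array set too, so excluding chance there does not separate these.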
